A study of Mus musculus with 4 samples.

How the data were processed

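Total RNA of 4 mouse cell lines (NSC, NSCL61, OPC and OPCL61; 1 array each) was hybridised to 1-colour Agilent mouse miRNA arrays with the Cy3 dye, from 100 ng of RNA per array per the labels' protocols. Per the file headers all 4 arrays were on 1 slide and came from 1 scan, so that no slide or scan batch separated the lines. Per the submitters' processing notes the images were read with Agilent Feature Extraction 10.7.3.1. Per the file headers the processed signal intensity of a spot was background-subtracted and spatially detrended, without normalization between arrays, and the design was annotated on mm9. The table of values deposited for the whole series held the same intensity values (largest difference 0 over all spots). Per the file headers, flags of 0 or 1 mark spots that were outliers, saturated or well above background, and the software gives a total signal per miRNA.

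Each array held 45364 spots, of which 40920 belonged to 2645 probes for 1023 mouse miRNAs, with 10 to 40 spots per probe and up to 4 probes per miRNA. A further 135 probes for 57 viral miRNAs and 1000 negative control spots were kept for checks. Spots flagged as outliers were left out, between 1842 and 2365 mouse spots per array. Values below the lowest spot signal well above background of the array (16.29 to 18.20 units) were set to it, log2 was taken and replicate spots were averaged. Each array was scaled by its 75th percentile over the 182 probes well above background on all 4 arrays, and the shifts were centred on their mean. The shift in a comparison is the difference of 2 such shifts. The level of a miRNA was that of its brightest probe over the 4 arrays. A probe was well above background if at least 50% of its spots were, and a miRNA if any of its probes was. The median SD over spots was between 0.08 and 0.12 on the log2 scale, and it measures technical error within an array only.

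With 1 array per line no test between lines was possible. Counted as changed were miRNAs well above background in both lines that differed by at least 2-fold and by more than 2 times the spot standard error. Where 1 line was below background, the higher level was set against the larger of the lowest level among detected probes and the probe's own level, and a bound of at least 2-fold counted. Such values are written "at least". This was done for 4 comparisons. Glioma-initiating and precursor cells were also fitted together over both lineages with limma 3.58.1 in R 4.3.3 (lineage as a term, trended prior variance, Benjamini-Hochberg adjustment, threshold 0.05), which measures the spread between 2 lineages and not between replicate cultures. Nothing in the labels says that lines were cultured more than once.

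The miRNA lists (21) and marker lists for other cell types (8) were fixed before the data were examined, as were the comparisons and the alternatives not said to be added later. The lists were miR-17 to miR-92 and paralogous clusters, let-7, neural stem cell and neuronal, oligodendrocyte-lineage, astrocyte-associated, raised in glioma, lowered in glioma, p53-responsive, Dlk1-Dio3, the miR-297, miR-466, miR-467 and miR-669 group, pluripotency, the miR-322 and miR-503 cluster, miR-15 and miR-16, miR-29, miR-30, the miR-23, miR-27 and miR-24 clusters, the miR-99, miR-100 and miR-125 group, miR-181, Hox, the miR-183, miR-96 and miR-182 cluster, and the miR-130, miR-301, miR-148 and miR-152 group. Marker lists covered blood cells and microglia, endothelial cells, fibroblasts with pericytes and smooth muscle, muscle, epithelium, hepatocytes, neurons and endocrine cells. A list's median change was ranked among 10000 random lists of the same size matched on deciles of mean signal, for lists with at least 3 measured members, as a description of these arrays. Lists overlap, and their names follow textbook use. The miR-297, miR-466, miR-467 and miR-669 group had been fixed as the intronic cluster of Sfmbt2, but was chosen by name, and some members lie elsewhere.

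Named miRNAs were chosen by a rule written beforehand. It took the 10 largest rises and falls and the 4 largest bounds per direction in each comparison of glioma-initiating with precursor cells, and 6 and 3 in the other comparisons. It also took 8 shared miRNAs per direction, the 8 smallest adjusted p, the 2 brightest members of each list and its 2 largest changes in each lineage, and miR-340-5p and miR-340-3p. miRNAs named outside it, chosen after their values were seen, are miR-199b-5p, marker miRNAs singled out in a count, and those that changed in opposite directions. The text gives values for only part of the miRNAs that the rule took. Left out, among others, are miR-1937b, which the rule took in 1 comparison, and list members such as miR-34a-5p, miR-494-3p and let-7c-5p. Names are those of the array's design.

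The limma fit was tested on simulated data. With the observed noise (SD 0.73 between lineages, estimated from these arrays) over 206 miRNAs, limma found 1% of 2-fold and 13% of 4-fold changes, and with noise of 0.3 it found 62% and 100%. The simulated noise had the same SD for every miRNA. In the data it can differ between miRNAs, so these rates may be too favourable.

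Alternatives were scaling over all probes, no scaling, quantile normalization, normexp background correction with an offset of 50, the mean over probes, the software's total signal per miRNA, the median over spots, the deposited value table, a call needing all spots, no filter and a threshold of 3-fold. For limma they were also the fit without lineage, without trend, on miRNAs detected on all 4 arrays and without each array. Added after seeing the data were scaling by the median and, for limma, 1 common floor. Genome positions were taken from the array's mm9 annotation. Analyses used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.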

Results

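MicroRNA levels were measured in 4 mouse cell lines, with 1 array per line. NSC are neural stem cells, which give rise to neurons, astrocytes and oligodendrocytes. OPC are oligodendrocyte precursor cells, which normally form myelinating oligodendrocytes. NSCL61 and OPCL61 are glioma-initiating cells, which can start a glioma, derived from NSC and from OPC, respectively. The array held 2645 probes for 1023 mouse miRNAs, with a median of 20 replicate spots per probe. No line had a replicate array, so errors given here are standard errors or SDs over spots of 1 array. No mouse miRNA spot was saturated. Of the 1023 miRNAs, 170 were well above background in NSC, 228 in NSCL61, 139 in OPC and 206 in OPCL61, and 105 were so on all 4 arrays. Summed over the miRNAs well above background, the unscaled signal was 77997 units in NSC, 251259 in NSCL61, 32111 in OPC and 95031 in OPCL61. Signals were scaled between arrays, by log2 shifts of −0.52 for NSC, 1.44 for NSCL61, −1.30 for OPC and 0.38 for OPCL61. These shifts are large, so each change below is a change relative to the upper quartile of the shared miRNAs of its array, not per cell or per unit of RNA. The number of arrays limits the precision of every comparison, and no p-value between single lines is given.

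NSCL61 was set against NSC to ask which miRNAs distinguished glioma-initiating cells of neural stem cell origin from the stem cells themselves. NSCL61 had far less miR-9, which regulates neural progenitor proliferation and neurogenesis: miR-9-3p was 65.8-fold lower than in NSC (log2 change −6.04, spot SE 0.02; −5.01 relative to the median miRNA) and miR-9-5p was 20.7-fold lower (−4.37, spot SE 0.02). The miR-29 family, known for repressing collagen and other matrix transcripts, rose, with miR-29a-3p 25.5-fold, miR-29b-3p 20.1-fold and miR-29c-3p 5.38-fold higher. miR-21-5p, which is raised in many tumours, was 14.3-fold higher. In all, 29 miRNAs were higher and 95 lower by at least 2-fold among the 245 well above background in either line. The median log2 change of the 153 measured in both was −1.03, after a scaling shift of 1.95 between the lines; without scaling that median was 0.93, with scaling over all probes 0.90, with quantile normalization −0.36 and with median scaling −0.36.

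Among the other rises measured on both arrays, miR-24-3p was 6.01-fold higher, miR-7a-5p 5.86-fold, miR-27a-3p 4.66-fold, miR-22-3p 4.55-fold, let-7e-5p 3.43-fold and miR-23a-3p 3.26-fold. Some miRNAs were well above background in NSCL61 and not in NSC. Of these, miR-31-5p was at least 22.5-fold higher, miR-221-3p, a repressor of the cell cycle inhibitor p27, at least 14.1-fold, miR-96-5p at least 11.6-fold and miR-23b-3p at least 6.79-fold. The falls measured on both arrays included miR-3095-3p at 27.7-fold lower, miR-1892 at 12.9-fold, miR-714 at 12.5-fold and miR-1839-3p at 11.2-fold, and also miR-3082-5p at 9.54-fold. miR-181a-5p, miR-181b-5p and miR-181d-5p fell by nearly the same amount, 10.2-fold, 10.1-fold and 9.87-fold. miR-219-5p, which promotes oligodendrocyte differentiation, was at least 14.7-fold lower and not well above background in NSCL61. miR-882 was at least 9.64-fold lower, miR-3472 at least 8.05-fold and miR-124-3p, an abundant miRNA of neurons, at least 6.97-fold.

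Grouped by lists fixed before the data were examined, the miR-29 family (3 of 4 measured members higher, median log2 change 3.38) lay above 99.95% of random lists matched on signal. All 5 measured members of the miR-23, miR-27 and miR-24 clusters rose (median 2.24, percentile 99.2), as did miR-96-5p, miR-183-5p and miR-182-5p among the 4 measured members of the miR-183, miR-96 and miR-182 cluster (median 2.02, percentile 99.7), with miR-183-5p at least 4.53-fold and miR-182-5p at least 3.65-fold higher. In these lists, measured means well above background in either line, and medians include bounds. No member of the miR-183, miR-96 and miR-182 cluster was well above background in both lines, so its median is one of bounds. Of 10 measured miRNAs that textbooks list as raised in glioma, 5 rose and 1 fell (median 1.14, percentile 99.9). The astrocyte-associated list, which shares its miR-29 members with the family above, had 3 of 6 higher (percentile 99.5). The oligodendrocyte-lineage list had 2 of 7 higher and 2 lower (percentile 98.1, with 4 higher and 1 lower without scaling). Its 2 higher members, miR-23a-3p and miR-23b-3p, are shared with the miR-23, miR-27 and miR-24 clusters. Its 2 lower members were miR-219-5p and miR-338-3p (log2 change −1.59). Of 5 measured miR-181 family members 4 fell, and the median of −3.30 lay at percentile 0.07. Of 12 measured neural stem cell and neuronal miRNAs 7 fell and 1, miR-7a-5p, rose, with a median of −1.57 that turned to 0.18 without scaling, at percentile 13.6. The glioma-lowered textbook list, which shares the miR-181 members, had 6 of 12 lower and 1 higher at percentile 15.4, with a median of −1.04 that turned to 0.14 without scaling.

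The remaining lists lay inside the central 95% of random lists. The let-7 family had 1 of 11 measured members higher and 2 lower (median −0.45, and 1.38 without scaling), the miR-17 to miR-92 and paralogous clusters 2 of 11 lower (without scaling 8 higher and 0 lower, median 1.83), the miR-297, miR-466, miR-467 and miR-669 group 7 of 15 lower (without scaling 4 higher and 0 lower), with miR-466h-3p 7.67-fold lower, and the miR-30 family 2 of 5 lower (median −0.94, and 1.02 without scaling). The p53-responsive list had 2 of 5 lower (median −0.48, and 1.45 with scaling over all probes), the miR-15 and miR-16 family 2 of 6 higher (6 without scaling), the miR-99, miR-100 and miR-125 group 2 of 6 higher and 1 lower (5 and 0 without scaling), and the miR-130, miR-301, miR-148 and miR-152 group 2 of 5 lower (median −0.68, and 1.28 without scaling), with miR-130b-3p 8.94-fold lower. None of the 3 measured members of the Dlk1-Dio3 cluster or of the 5 of the miR-322 and miR-503 cluster passed the rule, while without scaling 2 and 4 were higher. With under 3 measured members, no percentile was taken for the Hox clusters, where miR-10b-5p was at least 2.71-fold higher, or for the pluripotency clusters, where neither of 2 members passed. Among marker lists for other cell types, fibroblast, pericyte and smooth muscle miRNAs had 2 of 4 measured members higher in NSCL61 (percentile 99.8; 4 without scaling), miR-199a-3p at least 5.95-fold and miR-199b-5p at least 2.06-fold. No member of the fibroblast, pericyte and smooth muscle list was well above background in both lines, and miR-143 and miR-145 were so in neither. The epithelial miRNA miR-205-5p was at least 4.30-fold higher, the only 1 of 14 on its list well above background in either line. All 3 measured neuronal markers fell, including miR-129-2-3p by 5.77-fold, and 0 fell without scaling. Endocrine miR-7a-5p rose, the single measured blood cell and endothelial markers did not pass (without scaling the blood cell one was higher, at 1.93), and no muscle or hepatocyte marker was well above background in either line.

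The balance of higher and lower miRNAs depended on the scaling. It was 29 against 95 here, 49 against 73 with median scaling, 45 against 57 with quantile normalization, 118 against 19 with scaling over all probes and 120 against 17 without scaling. All 29 higher calls and 17 of the 95 lower calls, among them miR-9-3p, miR-9-5p, miR-219-5p and the 3 named miR-181 members, stood under these 5 scalings, whereas miR-124-3p, miR-129-2-3p and miR-466h-3p did not, and without scaling 4 of the 12 neural miRNAs counted as higher and 3 as lower. The main shift of 1.95 was the largest, against 1.29 with median scaling, 0.03 with scaling over all probes and 0 without scaling. These alternatives could therefore only raise every change. Quantile normalization alone could have ended a higher call.

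**Figure D1:**
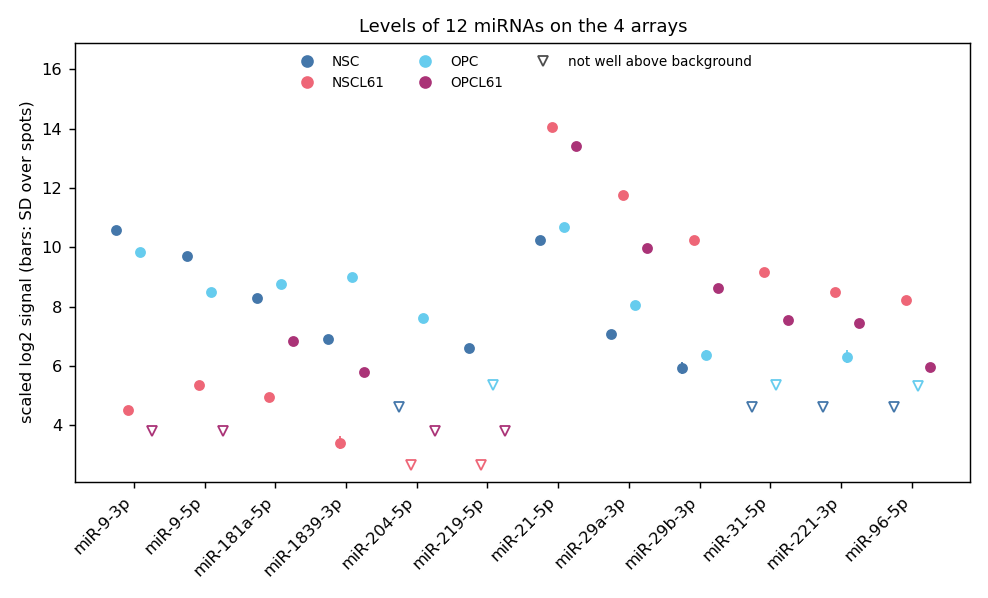
Scaled log2 signal of 12 miRNAs on the 4 arrays, with bars for the SD over replicate spots of 1 array, mostly smaller than the symbols; open triangles stand at the floor or at a level not well above background. miR-9-3p is at 10.57 in NSC and 4.53 in NSCL61, and miR-29a-3p at 7.08 in NSC and 11.75 in NSCL61.

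The same question was asked for the oligodendrocyte precursor lineage, by setting OPCL61 against OPC. miR-9 was lower here too: miR-9-3p was at least 64.3-fold lower and miR-9-5p at least 25.2-fold lower, neither being well above background in OPCL61. miR-204-5p, encoded within the ion channel gene Trpm3, was at least 13.9-fold lower. miR-21-5p had the largest rise measured on both arrays, 6.65-fold (log2 change 2.73, spot SE 0.02), and miR-29b-3p and miR-29a-3p rose 4.80-fold and 3.84-fold. Without scaling miR-9-3p was at least 20.1-fold lower and miR-21-5p 21.3-fold higher. By the same rule 31 miRNAs were higher and 44 lower among the 214 well above background in either line. The median log2 change of the 131 measured in both was −0.33 after a scaling shift of 1.68; it was 1.35 without scaling, 1.19 with scaling over all probes, −0.29 with quantile normalization and −0.40 with median scaling.

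The other largest rises were miR-150-3p at 5.88-fold, miR-2137 at 4.21-fold, miR-3098-5p at 4.11-fold, miR-3102-5p at 3.68-fold, miR-1894-3p at 3.34-fold, miR-3106-5p at 3.01-fold and miR-125a-5p at 2.95-fold. miR-31-5p was at least 4.43-fold higher, miR-758-5p at least 3.74-fold, miR-678 at least 3.68-fold and miR-125a-3p at least 3.08-fold, each not well above background in OPC. The largest falls measured on both arrays were miR-1839-3p at 9.11-fold, miR-503-5p at 5.76-fold and its cluster neighbour miR-322-5p at 5.54-fold. miR-99a-5p was 5.54-fold lower, miR-342-3p 4.99-fold, miR-20a-5p 4.29-fold, miR-20b-5p 4.25-fold, miR-487b-3p 4.15-fold, miR-331-3p 4.07-fold and miR-138-1-3p 4.06-fold. The neuronal miRNA miR-129-2-3p was at least 6.38-fold lower.

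Among the fixed lists, the miR-29 family had 2 of 3 measured members higher (median 1.94, percentile 99.5) and the astrocyte-associated list, which contains it, 2 of 4 higher and 1 lower (percentile 98.3; 3 and 0 without scaling). The X-linked miR-322 and miR-503 cluster had 2 of 4 lower (median −1.24, percentile 1.5), and the miR-17 to miR-92 and paralogous clusters, which drive proliferation in several tumours, had 4 of 10 lower, miR-20a-5p, miR-20b-5p and miR-92a-3p among them (median −0.91, percentile 2.30, and a median of 0.47 without scaling). Over the members well above background in both lines these medians were −2.50 (2 members) and −1.21 (8 members). The miR-181 family had 3 of 4 lower, with miR-181a-5p at 3.83-fold and miR-181b-5p at 3.55-fold (percentile 4.90; median −1.65, and 0.02 without scaling), and the neural list 4 of 8 lower (percentile 2.94, and outside the central 95% of random lists without scaling; median −0.97, and 0.28 without scaling). Of the textbook lists, miRNAs raised in glioma had 3 of 8 higher and 1 lower (percentile 90.1; 6 and 0 without scaling) and those lowered in glioma 5 of 10 lower (percentile 3.94; median −0.64, and 0.36 without scaling). The miR-23, miR-27 and miR-24 clusters had 2 of 5 higher and 1, miR-23b-3p, lower, whose change was 0.52 without scaling. The let-7 family had 4 of 11 lower (median −0.73, and 0.95 without scaling), the miR-30 family 2 of 5 lower (median −0.90, and 0.78 without scaling), the oligodendrocyte-lineage list 1 of 5 higher and 2 lower (2 and 0 without scaling), and the miR-15 and miR-16 family 1 of 6 in each direction (without scaling 5 higher and 0 lower, median 1.69). The Dlk1-Dio3 cluster had 2 of 5 higher and 1 lower (4 and 0 without scaling), the p53-responsive list 1 of 6 lower (median −0.04, and 1.12 without scaling), the miR-99, miR-100 and miR-125 group 2 of 6 higher and 1 lower (5 and 0 without scaling), the miR-130, miR-301, miR-148 and miR-152 group 1 of 4 lower (median −0.46, and 0.84 without scaling) and the pluripotency clusters 1 of 3 lower (1 higher and 0 lower without scaling). No measured member of the miR-297, miR-466, miR-467 and miR-669 group, of the Hox list or of the miR-183, miR-96 and miR-182 list passed, while without scaling 2, 1 and 2 were higher. Of the marker lists, 1 of 2 measured blood cell miRNAs (miR-150-3p) rose, the single measured neuronal one fell, neither of 2 fibroblast miRNAs nor the endocrine one passed (without scaling both blood cell miRNAs and the endocrine one, at 1.76, were higher and the neuronal one did not pass), and no endothelial, muscle, epithelial or hepatocyte miRNA was well above background in either line. The other arm of miR-150 was not well above background in either line.

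The counts of 31 higher and 44 lower became 29 and 47 with median scaling, 32 and 42 with quantile normalization, 109 and 6 with scaling over all probes and 119 and 4 without scaling. Of the calls, 28 higher and 4 lower (miR-9-3p, miR-9-5p, miR-204-5p and miR-1839-3p) stood under all 5 scalings, and without scaling no member of the miR-181 family or of the miR-322 and miR-503 cluster was lower. The main shift of 1.68 was close to the largest, 1.75 with median scaling. The other shifts were 0.16 with scaling over all probes and 0 without scaling, so these alternatives could hardly end a higher call.

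**Figure D2:**
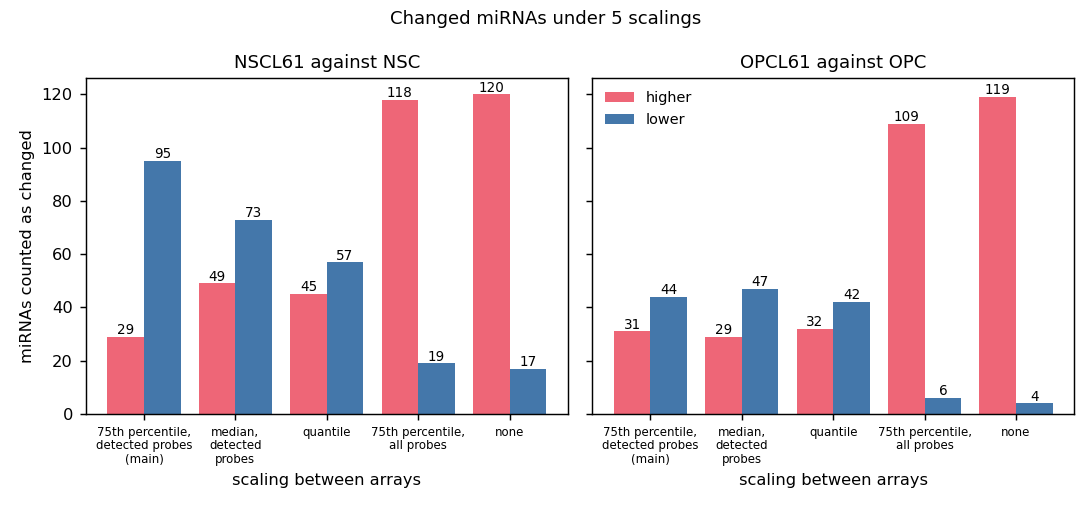
Number of miRNAs counted as higher (red) and lower (blue) in glioma-initiating cells against their precursors under 5 scalings between arrays; each bar is a count from 1 array per line. Higher calls in NSCL61 run from 29 with the main scaling to 120 without scaling.

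The overlap of the comparisons asked which miRNAs changed alike in glioma-initiating cells of either origin. Higher in both lineages were 11 miRNAs, led by miR-21-5p, miR-29b-3p, miR-31-5p, miR-29a-3p, miR-125a-5p, miR-22-3p, miR-3102-5p and miR-195-5p; of the 188 miRNAs measured in both comparisons 28 were higher in each, and independent lists of that size would share 4.17. miR-22-3p rose 4.55-fold in NSCL61 and 2.59-fold in OPCL61, miR-125a-5p 2.96-fold and 2.95-fold, and miR-195-5p at least 3.1-fold and 2.48-fold. Lower in both were 20, against 14.8 for independent lists of 73 and 38, led by miR-9-3p, miR-9-5p, miR-1839-3p, miR-129-2-3p, miR-342-3p, miR-99a-5p, miR-181a-5p and miR-181b-5p. miR-342-3p was 4.43-fold lower in NSCL61 and 4.99-fold lower in OPCL61, and miR-99a-5p 3.94-fold and 5.54-fold lower. Changes in opposite directions were seen for 10 miRNAs, against 16.5 for independent lists. Across the 105 miRNAs measured on all 4 arrays, which are not independent replicates, the changes in the lineages had a Pearson r of 0.40 and a Spearman rho of 0.33. Without scaling 63 rises and 3 falls were shared, against 58.1 and 0.223 for independent lists, and with scaling over all probes 59 and 3, against 52.7 and 0.399. Under all 5 scalings 10 of the 11 shared rises stood, but only 3 of the 20 shared falls, miR-9-3p, miR-9-5p and miR-1839-3p. Since the main shifts were at or near the largest in both lineages, most alternatives raised every change. That the rises stood follows largely from this and is no separate support for them.

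**Figure D3:**
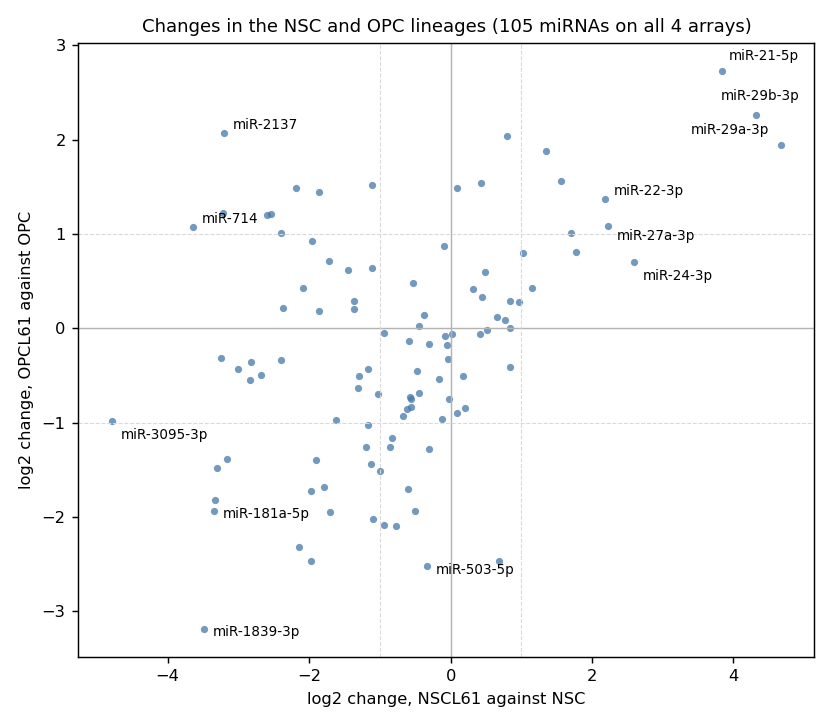
Log2 change in NSCL61 against NSC (x axis) and in OPCL61 against OPC (y axis) for the 105 miRNAs well above background on all 4 arrays, each point 1 miRNA and dashed lines at 2-fold. miR-21-5p, miR-29a-3p and miR-29b-3p lie at the upper right and miR-1839-3p, at −3.49 and −3.19, at the lower left; miR-9 is absent because it was not well above background in OPCL61.

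A limma fit of glioma-initiating against precursor cells, with lineage as a term and 2 arrays per state, covered the 206 miRNAs well above background on at least 2 arrays. miR-9-3p alone passed the adjusted p threshold (log2 change −6.03, SE 0.51, limma adjusted p = 0.0417), lower in 2 of 2 lineages, with OPCL61 at its signal floor; over the other settings its adjusted p ran from 9.31e-13 to 0.490. The next was miR-9-5p (−4.53, limma adjusted p = 0.0987), and among those at an adjusted p of 0.115 were miR-1839-3p, miR-29b-3p and miR-702. Also at 0.115 were miR-877-3p, miR-3092-3p and let-7b-3p, which were not well above background in NSC; their log2 changes in the NSC lineage lay within 0.03 of the gap between the floors of its arrays (−1.93), so that they are no measured changes there. At an unadjusted p under 0.05 limma listed 50 miRNAs, 10 higher and 40 lower, a split that turned to 53 and 2 without scaling and to 46 and 2 with scaling over all probes. Of the 40, 30 were not well above background on at least 1 array, and after scaling the floors of the glioma-initiating arrays lay below those of their precursors (log2 differences −1.93 and −1.52). With a common signal floor for the 4 arrays no miRNA was called (5 higher and 11 lower at an unadjusted p under 0.05), although miR-9-3p stayed at a log2 change of −4.88 (SE 0.34), and other settings gave from 0 to 50 calls.

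OPC and NSC were compared to ask how the precursor lines differed. OPC had more of several miRNAs: miR-652-5p was 20.9-fold higher, and miR-487b-3p, miR-138-1-3p and miR-3106-5p, not well above background in NSC, were at least 14.5-fold, 11.6-fold and 10.8-fold higher. miR-3098-5p was higher by 4.77-fold, miR-1839-3p 4.26-fold, miR-503-5p 4.05-fold, miR-322-5p 2.84-fold and miR-301a-3p 2.41-fold. Lower in OPC were miR-2137 (5.23-fold), miR-5097 (4.42-fold), miR-714 and miR-2861 (4.01-fold each), miR-149-3p (3.55-fold) and miR-211-3p (3.36-fold), and miR-135a-1-3p, miR-680 and miR-1982-5p, not well above background in OPC, were at least 4.58-fold, 4.13-fold and 2.47-fold lower. In total 28 miRNAs were higher and 23 lower among the 200 well above background in either line, after a scaling shift of −0.78. The miR-15 and miR-16 family had 2 of 6 measured members higher (percentile 98.2; median 0.73, and −0.06 without scaling), and the miR-297, miR-466, miR-467 and miR-669 group 2 of 7 lower (percentile 0.30), miR-466i-5p and miR-467f, whose genes lie within Cdk13 and Fxr2. Without scaling the counts were 12 and 64, with scaling over all probes 14 and 58, and 12 higher and 20 lower calls stood under all 5 scalings, with miR-322-5p and miR-301a-3p not among them. The main shift was close to the lowest, −0.79 with median scaling, so the shift-type alternatives could hardly end a lower call. The probes of miR-714 disagreed in sign.

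OPCL61 and NSCL61 were compared to ask how the glioma-initiating lines differed from each other. OPCL61 had 81.9-fold more miR-3106-5p, 43.3-fold more miR-1940, 23.4-fold more miR-1894-3p, 19.8-fold more miR-365-2-5p, 19.4-fold more miR-652-5p and 11.4-fold more miR-3098-5p. The first 4 had scaled log2 levels of 2.82 to 3.42 in NSCL61, near its floor of 2.68, so their folds are uncertain. Without scaling these 4 were 39.3-fold, 20.8-fold, 11.2-fold and 9.51-fold higher. miR-150-3p, miR-758-5p and miR-678 were at least 43.9-fold, 23.7-fold and 23.6-fold higher, not being well above background in NSCL61. OPCL61 had less miR-5097 (6.49-fold), miR-182-5p (6.03-fold), miR-199a-3p (5.75-fold), miR-96-5p (4.80-fold) and miR-720 (3.78-fold), and miR-205-5p, miR-199a-5p and miR-9-5p were at least 7.75-fold, 3.47-fold and 2.87-fold lower. The whole comparison gave 89 higher and 31 lower among 256 miRNAs, after a scaling shift of −1.06. The miR-183, miR-96 and miR-182 cluster (3 of 4 lower, percentile 0.04), the fibroblast, pericyte and smooth muscle markers (4 of 4 lower, percentile 0.15), the astrocyte-associated list (3 of 6 lower, percentile 0.315), the miR-29 family (3 of 4 lower, percentile 0.545) and the miR-23, miR-27 and miR-24 clusters (3 of 5 lower, percentile 1.36) lay at the low end of random lists. The miR-181 family (4 of 5 higher, percentile 98.95, and 0 of 5 higher without scaling), the Dlk1-Dio3 cluster (5 of 5 higher, percentile 98.4) and the blood cell markers (2 of 3 higher, percentile 97.7) lay at the high end. Quantile normalization gave 42 higher and 49 lower, median scaling 52 and 71, scaling over all probes 32 and 104 and no scaling 40 and 101. Of the calls, 30 higher and all 31 lower stood under the 5 scalings. The main shift of −1.06 was the lowest (−0.33 with median scaling), so that of the alternatives quantile normalization alone could have ended a lower call.

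Among the pairs of lines, NSC and OPC were the most alike. Over the 105 shared miRNAs the Pearson r of the log2 levels was 0.866 between NSC and OPC (95% interval over miRNAs 0.809 to 0.907), 0.806 between NSCL61 and OPCL61 (0.726 to 0.864, overlapping the first interval), 0.800 between OPC and OPCL61 and 0.723 between NSC and NSCL61 (0.617 to 0.804). It was 0.721 between NSCL61 and OPC and 0.768 between NSC and OPCL61, and no difference between these values was tested.

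miR-340-5p and miR-340-3p, chosen in advance whatever their values, were not well above background on any array, so that no fold is given. Of the 40 spots of miR-340-5p 1 was well above background in NSC, and its median signal there was 10.9 units, against −0.54 in NSCL61, 3.93 in OPC and 4.11 in OPCL61. The scanner software's own gene call counted miR-340-5p as detected in NSC and on no other array.

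In the mouse genome build mm9, per the file headers, the probe for miR-9-3p lay at 3 loci, on chromosome 3 at 88019577 to 88019595, on chromosome 7 at 86650207 to 86650225 and on chromosome 13 at 83878466 to 83878484. The probe for miR-21-5p lay on chromosome 11 at 86397588 to 86397607, that for miR-29a-3p on chromosome 6 at 31012715 to 31012734, that for miR-31-5p on chromosome 4 at 88556493 to 88556509, that for miR-204-5p on chromosome 19 at 22825102 to 22825121 and that for miR-340-5p on chromosome 11 at 49883226 to 49883243. In the RefSeq gene table of a later assembly, GRCm38.p6, used for names only, the miR-9 genes lay within noncoding RNA genes, the miR-21 gene within the span of Vmp1, the miR-204 gene within Trpm3 and the miR-340 gene within Rnf130, and no other gene spanned the miR-29a gene; exons and introns were not analysed here.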

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

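The tests of explanations in this part were chosen after the results were seen; the count of viral probes was not. Where a test parts the 10 miRNAs below, the parts were formed by its own values. These 10 changed in opposite directions in the lineages; with 1 array per line the difference itself was not tested. Values are the log2 change in NSCL61 against NSC minus that in OPCL61 against OPC. miR-2137 stood at −5.28, miR-714 at −4.72, miR-1940 at −4.43, miR-1224-5p at −3.81, miR-211-3p at −3.76, miR-188-5p at −3.67, miR-1895 at −3.41, miR-149-3p at −3.31 and miR-2861 at −2.64, all lower in NSCL61 and higher in OPCL61. miR-23b-3p, at least 3.92 in the other direction, was higher in NSCL61 and lower in OPCL61.

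Their probes had a median GC content of 71.0%, against 52.9% for the 188 miRNAs measured in both comparisons (above 99.8% of random sets of their size), and over 105 miRNAs the difference of the changes had an r of −0.46 with probe GC. Per 10 percentage points of GC the log2 change moved by −0.30 in the NSC lineage and 0.16 in the OPC lineage. This trend was taken over all miRNAs measured on both arrays, so it bears on the other changes too. After a linear GC trend was taken out of each comparison, 4 of the 10 (miR-188-5p, miR-1940, miR-2137 and miR-23b-3p) stayed past 2-fold in opposite directions by more than 2 spot standard errors. A linear trend thus does not account for the whole of these 4. They were picked by this outcome, and spot errors cover 1 array per line only, so other GC effects are not excluded. For the other 6 a GC-dependent signal stays open: 5 kept opposite signs, but the rises of the 6 in OPCL61, 1.01 to 1.52 before, were 0.59 to 0.99 after and so under 2-fold, and their falls of −3.64 to −1.12 became −2.73 to 0.23 (spot SE at most 0.08). For 9 of the 10 the difference stayed at 2.57 or more under all 5 scalings (1.90 for miR-2861, where opposite 2-fold changes need 2). All scalings but quantile normalization move every difference by the same amount. They therefore say only that shifts of their size cannot make these differences. The scaling is argued against as the source of the directions for 2, miR-1940 and miR-2137, which stayed opposite under all 5. For the directions of the other 8, of which 5 kept opposite signs without scaling (miR-714 kept both calls under all 5, but with its lowest rise within 2 spot standard errors, of 0.05 each, of 2-fold), and for the difference of miR-2861 the scaling stays open, as does a difference between the lineages, untested by a replicate.

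Both glioma-initiating arrays had a higher unscaled miRNA signal than their precursors. A higher scanner gain is argued against by the negative control spots: their net raw signal differed by at most 0.13 on the log2 scale between a line and its precursor, while the miRNA scaling shifts differed by 1.95 and 1.68. Labelling or hybridization efficiency cannot be told apart from a higher miRNA share of total RNA, since control probes named dmr, which would show it if their targets had been added, were well above background in 0 to 3 of 240 spots per array. Of the other control probes 5 were well above background in every spot. Their median log2 change was 1.31 in the NSC lineage (−0.42 to 1.80) and −0.24 in the OPC lineage (−0.62 to 0.70), below the shift of 1.68 there, but the sources used here do not say whether their targets were added in equal amounts. A further control, named miRNABrightCorner30, was well above background in 252 of 362 spots in NSCL61, against 7 in NSC, 1 in OPC and 0 in OPCL61. The cause of this was not tested. The biological reading, more miRNA per unit of RNA in the glioma-initiating lines, stays open and was not tested.

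Probes for viral miRNAs, outside the comparisons, were well above background in 8 cases in NSC, 12 in NSCL61, 7 in OPC and 14 in OPCL61, of 135 probes. The highest median signal of a viral probe was 133 units, in NSCL61, and no explanation was tested. Of 1000 negative control spots, 4 or 5 per array were well above background, a far smaller share. The viral miRNA mghv-miR-M1-2-3p was called on all 4 arrays. Viral miRNAs should not be expressed in cultured mouse cells, so the viral calls, 5.2% to 10.4% of the probes, were probably made without the viral target. What these probes bound was not tested. Counted per miRNA and not per probe, 4 of 57 viral miRNAs were called in NSC, 6 in NSCL61, 3 in OPC and 8 in OPCL61. Of the 1023 mouse miRNAs 170, 228, 139 and 206 were called, which is 13.6% to 22.3%. Calls of dim mouse miRNAs, and the falls and bounds that rest on them, share this limit. In NSC the brightest viral probe had 65.3 units, and miR-882, miR-3472 and miR-124-3p, among others, were dimmer there before scaling.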

How the results depend on the processing

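Median scaling and the common floor were chosen after seeing the data. The split into higher and lower calls moved with the scaling. Without scaling, the calls (higher, then lower) were 120 and 17 in NSCL61 against NSC, 119 and 4 in OPCL61 against OPC, 12 and 64 in OPC against NSC and 40 and 101 in OPCL61 against NSCL61, with 63 and 3 shared by the lineages and 23 in limma. Scaling over all probes gave 118 and 19, 109 and 6, 14 and 58, and 32 and 104, with 59 and 3 shared and 14 in limma. Quantile normalization gave 45 and 57 in NSCL61 against NSC, 42 and 49 in OPCL61 against NSCL61, 12 shared falls and 5 in limma; median scaling gave 49 higher, 52 and 71, and 30. For no scaling, scaling over all probes and median scaling the cause of the moved splits lies in the construction, since they only set the zero of the scale. Quantile normalization also changes the spread, and its cause was not tested. Normexp gave 14 higher in NSCL61, 13 in OPCL61 against OPC, 10 and 9 in OPC against NSC, 15 lower in OPCL61 against NSCL61, 5 shared rises and 50 in limma. The software's total signal gave 74 higher, 75 higher, 69 lower, 83 lower, 24 shared rises and 3 in limma. The cause of these was not tested. No filter admitted values at the floor, whose ties differ between arrays by construction, and gave 899 lower in NSCL61, 876 lower in OPCL61 against OPC, 861 higher in OPCL61 against NSCL61 and 834 shared falls; the limma fit could not be made on it. A 3-fold threshold gave 13 and 25 in OPCL61 against OPC, 16 and 10 in OPC against NSC, 55 and 17 in OPCL61 against NSCL61, and 4 and 12 shared. OPC against NSC had 14 lower with the mean over probes and 15 with all spots required, which left viral probes at 4 in OPC and 8 in OPCL61.

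limma called 1 miRNA here. It called 35 with the mean over probes, 14 with all spots required, and 0 with the median over spots and without trend, where 49 and 45 had an unadjusted p under 0.05; the cause of these was not tested. It also called 0 on miRNAs detected on all 4 arrays (19) and with a common floor (16). By construction the first leaves out miR-9-3p, which was not well above background in OPCL61, and the second closes the gap between the array floors. There the change of miR-9-3p went from −6.03 (SE 0.51) to −4.88 (SE 0.34), and the call ended as limma's prior degrees of freedom went from 3.27 to 0.893, not because the change was lost. Leaving out each array in turn, without the lineage term, gave 0 to 37 calls: 0 without NSC (11 at an unadjusted p under 0.05), 7 without NSCL61, 0 without OPC (10) and 37 without OPCL61, the lone array of a state being assumed to vary like the other. The fit with no replicate block, meaning no lineage term, gave 1 call, as did the fit with it. The adjusted p of miR-9-3p passed under each of the 5 scalings and ran from 9.31e-13 without NSCL61 to 0.490 with a common floor.

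List medians lay outside the central range of random lists in 7 lists for NSCL61 and in 4 for OPCL61. No filter left 2 in NSCL61, the miR-29 family and the miR-183, miR-96 and miR-182 cluster, and 0 in OPCL61. In OPCL61 normexp left 1, the miR-29 family, and the mean over probes 2, the miR-17 to miR-92 clusters and, newly outside, the Dlk1-Dio3 cluster. Of the 4 there, the miR-17 to miR-92 clusters were also inside with quantile normalization, the astrocyte-associated list with the software's total signal and all spots required, and the miR-322 and miR-503 cluster with the total signal. Newly outside there, on the low side, were the neural list without scaling, with scaling over all probes and with the total signal, the miR-181 family with quantile normalization and the total signal, the glioma-lowered list with the total signal and let-7 with all spots required; on the high side, Dlk1-Dio3 with quantile normalization. The cause of these moves was not tested. The oligodendrocyte-lineage list in NSCL61 was inside the range with quantile normalization, normexp, the mean over probes, the software's total signal and all spots required. Without scaling and with scaling over all probes, in that order, signs reversed for miR-149-3p (0.088 and 0.060) and miR-2861 (0.84 and 0.81) in NSCL61, and for miR-23b-3p (0.52 and 0.36) and the miR-17 to miR-92 cluster median (0.47 and 0.31) in OPCL61. With no filter the list medians reversed for the oligodendrocyte-lineage and glioma-raised lists (both −1.93), the astrocyte-associated list (−1.91) and the miR-23, miR-27 and miR-24 clusters (−1.92) in NSCL61, and for the astrocyte-associated list and the miR-29 family (both −1.52) in OPCL61, through members at the floor. The deposited value table moved nothing, being identical. Signal over background limits what can be seen: 271 of 1023 miRNAs were well above background on at least 1 array.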

Other observations

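The tests of miRNAs encoded together were chosen after the results were seen; the lists were not. Some marker miRNAs of mesenchymal cells, miR-199 and miR-214, set the glioma-initiating lines apart. miR-199a-3p was well above background in NSCL61 and not in NSC. On the fibroblast, pericyte and smooth muscle list, 4 of 9 members were measured, miR-199a-3p, miR-199a-5p, miR-199b-5p and miR-214-3p. All 4 were lower in OPCL61 than in NSCL61, 2 of them well above background in both. miR-143 and miR-145, also on that list, were well above background in neither line. The epithelial miRNA miR-205-5p was well above background in NSCL61 only among the 4 lines. It was the only 1 of 14 on its list well above background in either glioma-initiating line. In the Dlk1-Dio3 imprinted cluster, 5 of 98 members on the array were well above background in either glioma-initiating line, and these 5 were higher in OPCL61, 4 of them without scaling.

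A hypothesis was that miRNAs encoded together change together. In OPCL61 against OPC, 9 pairs of miRNAs mapped within 10 kb of each other on 1 strand differed by a median of 0.36 on the log2 scale, against 1.26 for random pairs, at percentile 0.415 of 10000 random sets. Shared transcripts would give this, but other causes were not tested. In NSCL61 against NSC, 13 such pairs, among them most of those 9, differed by a median of 1.31, against 1.43 for random pairs, at percentile 37.6. The hypothesis thus found support in OPCL61 and none in NSCL61. Some miRNAs are in more than 1 pair. Both arms of a hairpin were measured in 5 cases in NSCL61 against NSC and 4 in OPCL61 against OPC, with miR-149 and miR-652 in both. In 1 of these 9 cases (miR-149 in OPCL61) the arms were called in opposite directions. With so few hairpins this decides nothing.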
